A study of Mus musculus with 12 samples.

How the data were processed

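The samples were 12 livers of mice at zeitgeber time 10, in 3 groups of 4 named by the labels. Total RNA was extracted with Trizol and cleaned with a column kit, and 1 microgram per liver went into a strand-specific total RNA library kit, per the labels' protocols. Per the submitters' processing notes, the tools were bcl2fastq 2.17, STAR 2.7.1a, SAMtools 1.9, featureCounts 2.0.1 and DESeq2 1.36.0, with build mm10. The strand setting of the counting is not given in the sources used here, so reads of a gene and of its antisense partner may not have been kept apart.

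The deposited table held 48537 genes. Its TPM values, a unit of transcript abundance scaled to the same total in each library, were computed by the authors. It also held the authors' log2 fold changes for 3 numbered comparisons that the file headers do not name, and an adjusted p-value for each, deposited by the authors.

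TPM is not a count, so the main test ran on log2(TPM + 1) and a fold change on that scale understates the change of genes with little RNA. Each TPM multiplied by the gene's length less a fixed offset was a whole multiple of 1 step per library, within a tolerance of 0.01 reads for 100% of values. Whole reads were recovered from these steps. They gave the depth of each library, between 5621667 and 6906221 reads, and served in alternatives. In pairs of replicate livers the chi-square per degree of freedom ran from 4.56 to 15.6, so no pair differed by as little as sampling noise. P-values measure the spread between the livers of a group.

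Genes with a mean TPM of at least 1 over all 12 libraries were tested, 17957 in all. limma 3.58.1 in R 4.3.3 fitted 3 group means to all libraries, with 9 residual degrees of freedom and a trend in the prior variance, two-sided, with Benjamini-Hochberg adjustment over the genes of each comparison and a threshold of 0.05. The 3 comparisons were livers labelled DKO against control livers, re-expression livers against livers labelled DKO, and re-expression livers against control livers. Gene lists were tested with fry from limma, which asks whether the genes of a list move, on balance, one way and compares them with no other genes. Its form without regard to direction was not among the fixed tests and called 21, 6 and 19 lists in the 3 comparisons. A second list test, camera, was run with a preset correlation, which called 10, 7 and 11 lists in the 3 comparisons, and with an estimated correlation, where the clock genes with ROR elements were the 1 list called in each. Other software was statmod 1.5.0, the data.table package in version 1.17.8, Python 3.11.15 and matplotlib 3.10.9. Single values of a library or gene were compared with exact permutation tests.

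The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except for 2 alternatives, fry without regard to direction and the tests of the closing section that are named as chosen later. The 35 lists held 419 genes, of which 418 were matched by symbol and 363 were tested, and 32 lists had at least 3 tested genes. The lists that were tested and not called between livers labelled DKO and control livers had fry adjusted p from 0.0801 to 0.91. No pancreatic acinar gene was tested, and 1 adipocyte gene was. The text may name Nr1d1 and Nr1d2, in each comparison the 10 called genes with the largest rise and the 10 with the largest fall among genes whose groups do not overlap, all tested clock genes, and up to 4 genes with the smallest p of each other list. Unnamed gene models were counted and not described. The rule admits 246 genes. From these 87 were picked after their values were seen for the checks of stability and of outlying livers, including genes with calls that were easily lost, and the text gives values for no gene outside them. The totals over all 246 genes are given beside those of the 87. Some genes of the rule are not reported here. Positions are from GENCODE release 21 for mouse, on mm10, which held 17918 of the 17957 tested genes.

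The procedure was tested on simulated reads for the comparison of livers labelled DKO with control livers, over 17862 genes. It called 58.6% of genes changed 2-fold and 96.9% of genes changed 4-fold in the right direction, and 8 of 17666 unchanged genes. A returned share made as 0.2, away from the value near 0.5 that shared livers give with no effect, came back as 0.211. It was made only in genes changed 2-fold or 4-fold with at least 10 reads, so it does not check the share of smaller changes.

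Alternatives were other pseudocounts, filters, scalings, sample quality weights, a robust prior, the 8 libraries of each comparison alone, the replicate number as a block, each library left out in turn, and a threshold on fold size. A filter of at least 10 recovered reads and voom on the recovered reads were added after the data were seen. DESeq2 and edgeR were not run. The authors' comparisons were used to describe their own calls, to give the fold changes of 4 genes, and to see by correlation which comparison described here each matches, and no column of per-sample values was left unmatched.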

Results

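The data were RNA-seq of whole mouse liver collected at zeitgeber time 10, that is 10 h after lights on. The labels gave 3 groups of 4 livers each: control livers, livers with a double knockout (DKO) of the REV-ERB genes, and DKO livers that re-expressed REV-ERBalpha. Sample titles name YFP for the control livers and the livers labelled DKO, and REV-ERBalpha-WT for the re-expression livers. The deposited column names were YFP, YFP_Cre and YFP_WT. By the titles, control livers and livers labelled DKO share YFP, so it does not set these groups apart. What the recombinase Cre does to liver RNA was not tested and cannot be told apart from REV-ERB by these groups. The same holds for YFP in comparisons with the re-expression livers, whose titles do not name it. REV-ERBalpha and REV-ERBbeta, encoded by Nr1d1 and Nr1d2, are nuclear receptors that repress transcription as part of the circadian clock. The labels describe each library as a separate biological replicate liver. Each library held between 5621667 and 6906221 recovered reads, and between 22240 and 23289 genes had at least 1 read. The 20 genes with the most RNA took at most 23.3% of a library's TPM, and mitochondrially encoded genes took between 5.71% and 7.38%. Of 12 exact permutation tests of these library measures between groups, the number of genes with a read gave the smallest p. It was 22780 ± 100.8 in the re-expression livers and 22533 ± 115 in the livers labelled DKO (SD, n = 4, exact two-sided p = 0.0286, the smallest that 4 against 4 allows and not adjusted). On the second principal component of all libraries control replicates 1 and 2 stood at 26.9 and 6.36 and replicates 3 and 4 at -43.8 and -48.7, with size factors of 1.056 and 1.055 against 0.933 and 0.952. Re-expression replicates 1 to 4 also fell in order, at 30.28, 4.828, -1.209 and -8.475. DKO replicates 1 to 4 did not, at 3.441, 12.35, -2.125 and 20.16. The cause of these orders and of the split among control livers was not tested.

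The REV-ERB genes themselves were examined first. Nr1d1 (chromosome 11, 98767932 to 98775333, minus strand, build mm10) stood at 68.7 ± 5.53 TPM in control livers, 82.5 ± 7.39 in livers labelled DKO and 191 ± 22.4 in re-expression livers (SD, n = 4). Nr1d2 (chromosome 14, 18204054 to 18239127, minus strand) stood at 96.6 ± 14.9, 90.4 ± 7.91 and 97.7 ± 15.2 TPM. Nr1d1 was 1.20 higher on the log2 scale in re-expression livers than in livers labelled DKO (exact two-sided permutation p = 0.0286, the smallest of 70 assignments). Neither gene was lower in the livers labelled DKO by more than the spread between livers: the difference was 0.26 for Nr1d1 (exact permutation p = 0.0571) and -0.09 for Nr1d2 (exact permutation p = 0.571). Values summed over a whole gene can keep reads from outside a deleted part, and the labels do not say which part was deleted, so they do not check the deletion. The group is therefore called the livers labelled DKO, and DKO in the name of a replicate or comparison means that label alone. Nr1d1 overlaps Thra on the opposite strand.

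The first comparison set livers labelled DKO against control livers, which addresses how liver RNA differs between these 2 labels. Of 6 clock genes with ROR elements, the DNA sites through which REV-ERB represses, 5 were called higher and 1 lower: Arntl, the gene of the clock activator BMAL1, went from 0.728 ± 0.205 to 19.8 ± 1.27 TPM, a 27.2-fold difference of means (SD, n = 4). Cry1, a repressor of the clock, was 5.99-fold higher and Nfil3, a repressor that acts on D-boxes, 4.75-fold higher. Cdkn1a, the cell cycle inhibitor p21, rose from 2.22 ± 0.507 to 53.4 ± 4.58 TPM. Called acute phase genes were lower, with serum amyloid Saa1 at 346 ± 280 TPM in control livers and 13.6 ± 2.92 TPM in livers labelled DKO. In limma's test of 17957 genes, 537 genes were called higher and 421 lower at a Benjamini-Hochberg adjusted p under 0.05, and 174 and 147 of them changed at least 2-fold on the log2(TPM + 1) scale. The groups did not overlap in 925 of the 958 called genes and in 11.5% of all tested genes, where chance gives 2.86%.

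All 6 clock genes with ROR elements were called, 5 of them higher (fry adjusted p = 4.66e-10, and adjusted p = 0.00216 with an estimated correlation). The count adjusted over the list alone was also 5 higher and 1 lower. Arntl (chromosome 7, 113207465 to 113314126) rose by 3.60 ± 0.11 on the log2(TPM + 1) scale (SE, adjusted p = 1.37e-08). Npas2 (chromosome 1, 39193731 to 39363236), the gene of a partner of BMAL1, rose by 3.70 ± 0.17 from a control mean of 0.0713 TPM (SE, adjusted p = 3.25e-07). Cry1 (chromosome 10, 85131700 to 85185064) rose by 2.46, Nfil3 by 2.22 and Clock by 1.08. Arntl and Npas2 each overlap an unnamed gene model on the opposite strand.

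The called clock genes driven through E-boxes and D-boxes went the other way. Of 14 tested, 7 were called lower and 0 higher, also when adjusted over the list alone (fry adjusted p = 0.000507, and adjusted p = 0.063 with an estimated correlation). Wee1, a kinase gene of cell cycle control, fell from 29.6 ± 5.47 to 9.13 ± 0.599 TPM, and Usp2 fell by 0.84 and Per3 fell by 0.71 on the log2 scale. Nampt, which encodes an enzyme of NAD synthesis, fell by 1.16 (adjusted p = 0.00433). Dbp, Per1 and Cry2 were not called, with log2 changes of -0.19, -0.24 and -0.19. The fall of Per2 by 0.43 (adjusted p = 0.0456) was lost without any 1 of control replicates 2, 3 and 4, DKO replicates 1 to 4 and re-expression replicates 2 to 4, and its adjusted p ran from 0.0256 to 0.115 over the alternatives. In all, 14 of 25 alternatives lost this call.

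**Figure D1:**
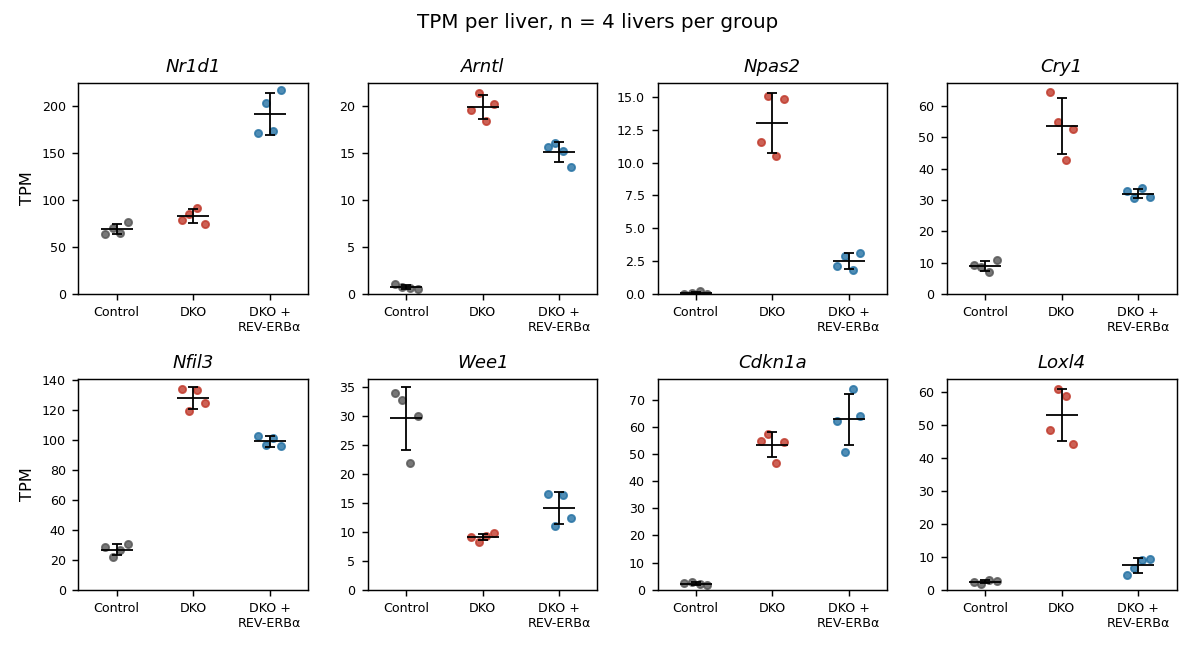
TPM of 8 genes in each liver, with each point a liver, the long horizontal bar the group mean and the error bar the SD (n = 4 livers per group, vertical axes from 0). Arntl, Cry1, Nfil3, Cdkn1a, Npas2 and Loxl4 were higher in all 4 livers labelled DKO than in all 4 control livers, Wee1 was lower, and Loxl4 and Npas2 stood closer to control in the re-expression livers.

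Of 16 genes of amino acid metabolism 7 were called higher and 0 lower, and 12 when adjusted over the list alone (fry adjusted p = 0.0013, and adjusted p = 0.134 with an estimated correlation). Gldc, the gene of the glycine cleavage enzyme, rose from 52.4 ± 7.8 to 177 ± 26 TPM, and Oat and Got1 rose by 0.71 and 0.75 on the log2 scale. In the cell cycle list 1 of 8 genes was called, the inhibitor gene Cdkn1a (chromosome 17, 29090976 to 29100727), also when adjusted over the list alone. The list's median change was 0.02 (fry adjusted p = 0.00109, 0.0815 with no filter on low values, 0.516 with a preset correlation, and adjusted p = 0.805 with an estimated correlation). Cdkn1a rose by 4.09 ± 0.14 (SE, adjusted p = 1.45e-08), and its product stops the cycle.

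Of 17 acute phase genes, 6 were called lower and 0 higher, and 12 lower and 1 higher when adjusted over the list alone (fry adjusted p = 0.033, and adjusted p = 0.459 with an estimated correlation). Saa1 fell by 4.29 ± 0.63, Saa2 fell by 4.39 ± 0.65 and Orm2, an orosomucoid gene, fell by 3.84 ± 0.62 (SE). Orm1 fell from 4002 ± 1127 to 1897 ± 148 TPM. The control livers spread widely, from 159 to 754 TPM for Saa1. The list's call was lost without control replicate 1 (adjusted p = 0.0988), control replicate 3 (0.0588) or DKO replicate 1 (0.0533), 2 (0.0665), 3 (0.0574) or 4 (0.0711). Among its members, the call of Hp was lost without control replicate 1 or 3 or DKO replicate 3 or 4 (adjusted p from 0.0517 to 0.0608), and that of Orm3 without control replicate 1 (0.0501) or DKO replicate 1 (0.0574) and with 8 libraries (0.0532). The Saa and Orm genes have near-identical copies, so reads can be split between them.

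**Figure D2:**
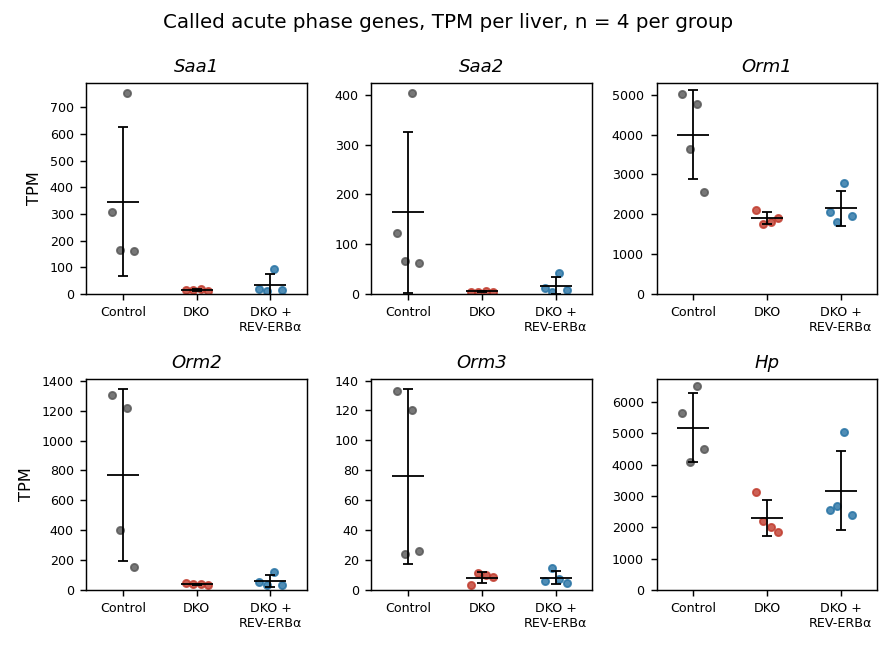
TPM of the 6 acute phase genes called lower in livers labelled DKO, with each point a liver, the long bar the group mean and the error bar the SD (n = 4 livers per group, vertical axes from 0). Saa1 ran from 159 to 754 TPM in control livers and reached 92.2 TPM in the highest of the other 8 livers, re-expression replicate 3.

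In lipid metabolism the called members went in both directions and fry called none of these lists with all libraries and the main settings. Opposite changes cancel in that test. Without regard to direction, fry gave adjusted p = 0.000683 for fatty acid synthesis, 1.76e-10 for oxidation and 7.24e-11 for lipid droplet genes. Of 20 genes of fatty acid oxidation, 4 were called lower and 1 higher (6 and 4 adjusted over the list alone; fry adjusted p = 0.291), among them Ppara, the gene of the receptor that drives this pathway, which fell from 256 ± 8.5 to 160 ± 8.76 TPM. Cpt1a fell by 0.64 on the log2 scale. Of 16 fatty acid synthesis genes 1 was called lower, the desaturase gene Fads2, and 5 were lower adjusted over the list alone (fry adjusted p = 0.0801, but 0.0485 with no filter on low values, 0.0358 with quantile normalization, 0.0418 without DKO replicate 1 and 0.000873 with a preset correlation). Fasn, the gene of fatty acid synthase, was not called (222 ± 24.2 and 112 ± 47.9 TPM, adjusted p = 0.0543, 0.0181 to 0.136 over the alternatives). It was called with a mean TPM of at least 5 (0.0395), quantile normalization (0.0428), at least 10 reads (0.0252) and voom (0.0181), and without DKO replicate 1 (0.0381) or 4 (0.0481) or re-expression replicate 1 (0.0457). Of 16 lipid droplet and lipoprotein genes 3 were called higher and 0 lower (3 and 2 adjusted over the list alone; fry adjusted p = 0.311), with Lpl 4.15-fold and Plin5 2.57-fold higher.

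Bile acid, glucose and xenobiotic genes were likewise mixed. Cyp8b1, the enzyme gene that directs bile acids to cholic acid, rose from 314 ± 58.5 to 762 ± 125 TPM, and 3 of 15 bile acid genes were called higher and 2 lower (3 and 5 adjusted over the list alone; fry adjusted p = 0.807). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 2.12 ± 0.52 (SE, adjusted p = 0.0366, 0.00836 to 0.0949 over the alternatives). That call was lost in 12 of 25 alternatives, among them those without any 1 control library, DKO replicate 1, 3 or 4 or re-expression replicate 1 or 2. Among 16 glucose genes, 2 were called higher and 3 lower (3 and 4 adjusted over the list alone; fry adjusted p = 0.867): the glycogen targeting genes Ppp1r3b and Ppp1r3c rose by 1.55 and 1.92, and the glucose transporter gene Slc2a2 fell by 0.46. Among 14 xenobiotic genes, 3 were called higher and 2 lower (3 and 4 adjusted over the list alone; fry adjusted p = 0.311), with Cyp2a5 2.01-fold and Gstm3 4.10-fold higher and a log2 change of -0.62 for Ugt1a1.

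Of the lists of other cell types, 3 were called by fry and none of these with an estimated correlation. Of 11 stellate cell and fibroblast genes 5 were called higher and 0 lower, and 9 adjusted over the list alone, with a median log2 change of 0.51 (fry adjusted p = 0.00326, and adjusted p = 0.134 with an estimated correlation). Reln rose by 0.77 and Lrat, a gene of retinoid storage, by 0.94. Of 6 cholangiocyte genes 2 were called higher, also adjusted over the list alone, with a median of 0.29 (fry adjusted p = 0.0166, and adjusted p = 0.459 with an estimated correlation), led by Sox9 with a rise of 1.70. That list's call was lost without DKO replicate 4 (adjusted p = 0.0552), with the replicate block (0.0594) and with a preset correlation (0.0839). Of 5 red blood cell genes 0 were called and 5 were higher adjusted over the list alone, with a median of 0.85 (fry adjusted p = 0.0365, and adjusted p = 0.459 with an estimated correlation); the call was lost without control replicate 1, 2 or 4, DKO replicate 1, 2 or 4 or re-expression replicate 2 (adjusted p from 0.051 to 0.118), and with size factors (0.0571), quantile normalization (0.0556), the replicate block (0.0923) and voom (0.0609). The 11 Kupffer cell genes had a median of -0.36 with 0 called (fry adjusted p = 0.311), and the 9 sinusoidal endothelium genes a median of 0.34 with 0 called and 5 higher adjusted over the list alone (fry adjusted p = 0.148, but 0.023 with 8 libraries and 0.0116 without re-expression replicate 2). With a preset correlation adjusted p was 0.0347 for the Kupffer cell list and 0.00387 for the sinusoidal endothelium list.

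Of 8 glucocorticoid response genes 3 were called higher and 1 lower, also adjusted over the list alone (fry adjusted p = 0.0365, and adjusted p = 0.459 with an estimated correlation). Tsc22d3 rose by 1.29 and Zbtb16 by 1.67. The list's call was lost without control replicate 1, 2 or 4, DKO replicate 1, 2 or 4 or re-expression replicate 4 (adjusted p from 0.0522 to 0.147), and with size factors (0.0571), quantile normalization (0.0562), weights (0.0534) and a preset correlation (0.13), and its median turned to -0.08 without control replicate 4.

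Other genes had large changes, among them Acot3 of the fatty acid oxidation list and Cyp2a4 of the female-biased list. Loxl4, a lysyl oxidase gene (chromosome 19, 42593982 to 42612813), rose from 2.46 ± 0.455 to 53.1 ± 8.02 TPM, and Hcn3 was 7.88-fold lower but overlaps Pklr on the opposite strand. Acot3 fell by 2.48. Cyp2a4 rose by 3.35 ± 0.81 (SE, adjusted p = 0.0353, 0.00994 to 0.0976 over the alternatives). That call was lost in 10 of 25 alternatives, among them those without any 1 control library, DKO replicate 1, 2 or 4 or re-expression replicate 2. Mup17 fell by 3.70, a call lost without control replicate 2 or 3 or DKO replicate 1, 3 or 4 (adjusted p from 0.052 to 0.0671). Both have close copies in the genome. The remaining 8 of the 20 largest changes were in unnamed gene models. Leaving out DKO replicate 1, 2 or 4 gave 337, 349 and 333 higher calls and 272, 280 and 242 lower calls, and leaving out control replicate 1 or 2 gave 263 and 274 lower calls. Of all called genes 80 had under 10 recovered reads per library, which is 1.7% of the tested genes with so few reads, against 6.6% called among the others.

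The second comparison set re-expression livers against livers labelled DKO, which addresses what returning REV-ERBalpha changes. Nr1d1 itself rose 2.32-fold. Loxl4 fell from 53.1 ± 8.02 to 7.43 ± 2.26 TPM and Npas2 from 13 ± 2.3 to 2.48 ± 0.613 TPM (SD, n = 4). Raet1d, a gene of a ligand of natural killer cell receptors, fell from 62.8 ± 18.9 to 14.6 ± 1.99 TPM. In limma's test 5 genes were called higher and 8 lower. At an unadjusted p under 0.05 there were 1111 genes, and 4.25% of all tested genes did not overlap, where chance gives 2.86%.

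The log2 changes were -2.71 ± 0.20 for Loxl4 (SE, adjusted p = 0.000271) and -2.01 ± 0.17 for Npas2 (adjusted p = 0.00063). Raet1d was 4.3-fold lower (adjusted p = 0.00405). Npas2 was not called with a pseudocount of 0.1 (adjusted p = 0.0572). Pyroxd2, Car14, Fam210b and the antisense gene Hectd2os also fell, and Acot4 and Prxl2a rose, all 6 opposite to their change in livers labelled DKO. Loxl4 and Pyroxd2 lie 113044 bases apart on chromosome 19. Bloodlinc was listed at 0 in all 4 livers labelled DKO and rested on 1.25 reads per library. The calls of Acot4, Prxl2a and Hectd2os were lost without any 1 of the 8 libraries compared, that of Fam210b also without control replicate 1 or 3, that of Bloodlinc without any 1 DKO library, that of Car14 without any but re-expression replicate 2, and that of Pyroxd2 without any 1 DKO library or re-expression replicate 2 or 4 (highest adjusted p 0.102, 0.119, 0.132, 0.17, 0.0754, 0.102 and 0.088 over the alternatives). Over all alternatives the calls of these genes, in the same order, were lost in 9, 8, 11, 13, 5, 7 and 7. Without DKO replicates 1 to 4 in turn there were 2, 1, 1 and 1 higher calls, without re-expression replicate 1, 3 or 4 there were 3, 1 and 1, and without DKO replicate 1, 2 or 4 there were 5, 4 and 5 lower calls.

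Among the fixed lists, 2 of 32 were called. The list of 6 clock genes with ROR elements was called in the lower direction, with 5 negative and 1 positive change, 1 gene called lower, and 4 lower and 1 higher adjusted over the list alone (fry adjusted p = 0.000184, and adjusted p = 0.0157 with an estimated correlation). Arntl was at 15.1 ± 1.09 TPM against 19.8 ± 1.27 in livers labelled DKO and was not called (adjusted p = 0.398), nor were Cry1 at 32 ± 1.47 against 53.6 ± 8.99 TPM (adjusted p = 0.113, but 0.0334 with weights and 0.011 with voom) and Nfil3 at 99.1 ± 3.58 against 128 ± 7.09 TPM (adjusted p = 0.26). The list of 14 E-box and D-box clock genes was called in the higher direction, with 12 positive and 2 negative changes, 0 genes called and 4 higher adjusted over the list alone (fry adjusted p = 0.0414, and adjusted p = 0.0954 with an estimated correlation). That call was lost without control replicate 1 or 4, any 1 DKO library or re-expression replicate 1, 3 or 4 (adjusted p from 0.0554 to 0.149), and with the replicate block (0.302). Cdkn1a was at 62.7 ± 9.5 TPM and was not called (adjusted p = 0.964). The 17 acute phase genes had a median change of 0.09 with 0 called (fry adjusted p = 0.896).

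The third comparison set re-expression livers against control livers, which addresses what stayed different. Cdkn1a stood 28.2-fold and Arntl 20.7-fold above control, and Chka, a gene of phosphatidylcholine synthesis, 5.54-fold and Lgalsl 5.91-fold. Saa1 fell by 3.58 ± 0.63 and Orm2 fell by 3.40 ± 0.62 on the log2(TPM + 1) scale (SE). In limma's test 208 genes were called higher and 119 lower. The groups did not overlap in 326 of these 327 genes and in 7.28% of all tested genes, where chance gives 2.86%. Without re-expression replicate 4 the counts were 125 and 50, and without control replicates 1 to 3 or re-expression replicates 1 to 3 in turn the lower calls were 68, 72, 77, 75, 67 and 76.

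All 6 clock genes with ROR elements were still called, 5 higher and 1 lower, also adjusted over the list alone (fry adjusted p = 5.03e-09, and adjusted p = 0.00146 with an estimated correlation). Of the E-box and D-box genes 2 of 14 were called lower and 6 adjusted over the list alone (fry adjusted p = 0.0309, and adjusted p = 0.271 with an estimated correlation), where Wee1 fell by 1.02. That list's call was lost without control replicate 1, 2 or 4, DKO replicate 1 or re-expression replicate 2 (adjusted p from 0.0503 to 0.0747), and with 8 libraries (0.0933) and the replicate block (0.0823). Cdkn1a was the 1 called gene of the cell cycle list, also adjusted over the list alone (fry adjusted p = 0.000236, 0.0586 with a preset correlation, and adjusted p = 0.338 with an estimated correlation).

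Amino acid genes were called as a list, with 2 higher and 6 adjusted over the list alone (fry adjusted p = 0.0395, and adjusted p = 0.306 with an estimated correlation); the call was lost without control replicate 1, 2 or 4, DKO replicate 1 or 4 or re-expression replicate 2, 3 or 4 (adjusted p from 0.0503 to 0.0933), and with size factors (0.177), the top 20 genes left out of the total (0.0554), 8 libraries (0.0933), the replicate block (0.0823) and voom (0.141). Gldc stood 2.78-fold above control. Stellate cell genes were called with 1 higher and 3 adjusted over the list alone (fry adjusted p = 0.0312, and adjusted p = 0.271 with an estimated correlation), a call lost without control replicate 1, 2 or 3, DKO replicate 1 or re-expression replicate 2 or 4 (adjusted p from 0.0509 to 0.0901) and with size factors (0.0661), 8 libraries (0.0933), the replicate block (0.0823) and voom (0.0645). Cholangiocyte genes were called with 1 higher and 2 adjusted over the list alone (fry adjusted p = 0.0167, and adjusted p = 0.271 with an estimated correlation), a call lost without control replicate 2 (adjusted p = 0.0501), with the replicate block (0.0823) and with voom (0.0645). Red blood cell genes had 0 called and 4 adjusted over the list alone (fry adjusted p = 0.0441, and adjusted p = 0.306 with an estimated correlation), a call lost without any 1 of 9 libraries, namely control replicates 1, 2 and 4, DKO replicates 1, 2 and 4 and re-expression replicates 2, 3 and 4 (adjusted p from 0.0586 to 0.104), and with no filter on low values (0.0579), size factors (0.0666), the top 20 genes left out of the total (0.0554), 8 libraries (0.0933), the replicate block (0.0952) and voom (0.0792). The acute phase list was not called (fry adjusted p = 0.0557), but was called without control replicate 4 (0.0229) or re-expression replicate 3 (0.0306), with a mean TPM of at least 5 (0.0495), quantile normalization (0.0473), at least 10 reads (0.0418) and a preset correlation (1.66e-08). Of its 17 genes 4 were called lower and 10 adjusted over the list alone. Among those 4, the call of Saa1 was lost without re-expression replicate 4 (adjusted p = 0.0521), that of Orm2 without re-expression replicate 2 or 4 (0.0551 and 0.0593), that of Saa2 without control replicate 1 or re-expression replicate 1, 2 or 4 (0.0634 to 0.0822) and that of Orm3 without control replicate 1 or 3, DKO replicate 2 or 4 or re-expression replicate 1, 3 or 4 (0.0504 to 0.106). With 8 libraries adjusted p was 0.0668 for Saa1, 0.0787 for Orm2, 0.102 for Saa2 and 0.0935 for Orm3. In all, 11 of 25 alternatives lost the call of Orm3.

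The return toward control was then measured over the 958 genes called between livers labelled DKO and control livers. Of these, 12 were called back, among them Loxl4, Npas2, Raet1d, Pyroxd2, Car14, Fam210b, Hectd2os, Acot4 and Prxl2a. The median share of the log2 change that was reversed was 0.284 for raised and 0.315 for lowered genes, and 0.301 for all. Both comparisons use the livers labelled DKO, so noise in these livers alone gives a return. This was simulated 50 times with no change in any gene, also none between livers labelled DKO and control livers. The genes with the smallest p were taken in the same numbers as the real calls, without a threshold. Among them the share was 0.505, a mean of 8.02 genes lay in both lists with opposite signs and 88.4% had the opposite sign, where 91.0% were observed. These simulated values do not show what a real change in livers labelled DKO with no return would give, so they do not judge the observed share. Independent lists would share 0.239 raised and 0.117 lowered genes. With the livers labelled DKO split into separate pairs, in 6 ways, the first pair chose the genes against control livers. The second pair was compared with re-expression livers. These comparisons share no library, so noise in the livers labelled DKO favors neither sign, and the simulated 88.4% is no reference for them. Of the genes, 76.3% to 86.1% had the opposite sign and 3 to 6 were called back. How far this percentage strays with no return was not simulated. The share, measured with the second pair and the same control livers, ran from 0.213 to 0.256. These fits called only 349 to 451 genes between livers labelled DKO and control livers, against 958 with all libraries. All libraries gave 12 genes called back, and leaving out DKO replicates 1 to 4 in turn gave 6, 4, 6 and 5, and leaving out re-expression replicate 3 or 4 gave 6 each. The covariance of the changes was -0.0965 against a simulated -0.0526, a difference of -0.0439.

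Of the same 958 genes, 282 were still called with the same sign in re-expression against control livers, 179 of the raised genes (33.3%) and 103 of the lowered genes (24.5%). These comparisons share the control livers: in the simulations with no change in any gene, lists of the same numbers of genes with the smallest p shared 108 genes of the same sign. Independent lists would share 6.22 and 2.79. The simulated 108 is not the number expected where livers labelled DKO do differ from control livers. The covariance was 0.138 against a simulated 0.0525, a difference of 0.0854. A further 45 genes, Nr1d1 among them, were called in re-expression against control livers and not in livers labelled DKO against control livers. This is not a test that they differ from the rest.

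**Figure D3:**
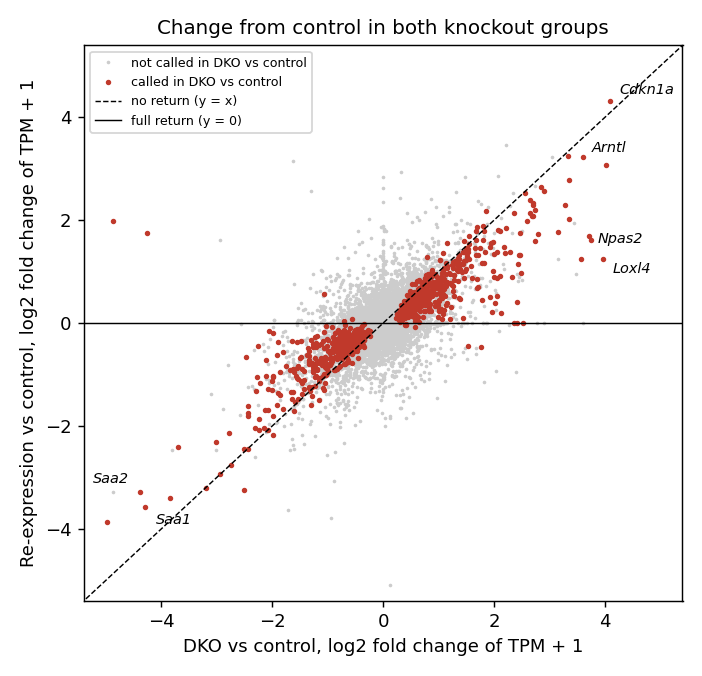
Log2 fold change of TPM + 1 against control for each of 17957 tested genes, in livers labelled DKO (horizontal axis) and in re-expression livers (vertical axis), with the 958 genes called in livers labelled DKO in red. Points on the dashed line did not return and points on the solid line returned fully, and Cdkn1a and Arntl lie near the dashed line while Npas2 and Loxl4 lie farther below it.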

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

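The tests of equal return with mixed cells, of acute phase genes and of gene length were chosen only after their results were seen. That the tests of scaling, of control livers with high acute phase RNA and of gene length decide nothing was also judged only then. The limits of the splits of libraries, of the test of equal return and of that of noise between livers were likewise judged only then. Of 273 groups of 4 livers checked for 1 liver far from the other 3, 20 had such a liver, where chance gives about 5% or 13.7. Over all 246 genes that the naming rule admits, 61 of 738 groups had one. The 20 are listed here with their TPM.

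In control livers these were replicate 4 for Dbp (78.8), replicate 3 for Bloodlinc (1.9), Hba-a1 (69.3) and Cps1 (3312), replicate 2 for Lpl (11.7) and Ppara (268), and replicate 1 for Serpina12 (6.32) and Slc10a1 (790). In livers labelled DKO they were replicate 1 for Acot3 (0.357) and Insig2 (265), replicate 3 for Ppp1r3c (113) and replicate 2 for Ppp1r3g (0.511). In re-expression livers they were replicate 3 for Hp (5046) and Fos (2.003), replicate 2 for Car14 (161), Gstm3 (462) and Sox9 (4.8), replicate 1 for Lpl (29.5), and replicate 4 for Cyp8b1 (806) and Hspb1 (10.5). In the authors' deposited table, comparison 3 had 210 genes with an adjusted p under 0.05, and it matched none of the 3 comparisons described (correlations across genes 0.281, -0.621 and -0.0154).

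Among the 35 splits of the 8 libraries of each comparison, 1, the real one, called as many genes, and fewer was not possible. The real and the highest other counts were 958 and 2, 13 and 2, and 327 and 3. Other splits mix livers of both groups, so where the groups differ the spread within a split is wider and fewer genes are called. With 35 splits these counts alone do not exclude chance.

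The first pattern was an unequal return among 137 genes raised at least 2-fold in livers labelled DKO with at least 10 reads, measured as the share of the TPM change that was reversed. The median was 0.343, and Loxl4 (0.902) and Npas2 (0.814) lay above it while Cdkn1a (-0.182) lay below. Full return in 1 share of the cells would give every gene the same share. The 95% intervals of 19 genes excluded the median, 16 above it and 3 below, where 6.85 are expected (exact binomial p = 5.67e-05). That p takes the genes as independent, but all were measured in the same livers, so it is too small if genes vary together. This count alone therefore does not exclude an equal share. Noise between livers would not be expected to repeat in other livers. Shares from replicates 1 and 2 and from replicates 3 and 4 had a Spearman correlation across genes of 0.537 (SE 0.0686, bootstrap over genes). That SE takes the genes as independent, and the genes were chosen with the same livers, so this 1 split does not exclude noise. The ranks with and without size factors correlated by 0.9998, but these factors ran only from 0.933 to 1.056 and could hardly move a rank, so that test excludes nothing. Whether and why genes differ stays open, and no test was made of a difference between genes in their response to REV-ERBalpha.

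The second pattern was the low acute phase RNA in both groups labelled DKO. In 4 of the 6 called genes the lowest control liver lay above all 8 other livers, but these genes were chosen for their lower values, and called genes had groups that did not overlap in 96.6%, so this excludes nothing. The list's median change was -0.71, and -0.56 without control replicate 1 and -0.76 without control replicate 3. Its call was lost without either (0.0988 and 0.0588), but also without any 1 DKO replicate (0.0533 to 0.0711), so the lost calls do not point to the control livers. Whether a few control livers with high values are the cause stays open. Whether another difference between control livers and the rest is the cause cannot be told apart from REV-ERB: the median share reversed by re-expression was 0.162 (jackknife SE 0.164), and 0.0219 without re-expression replicate 3.

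The third pattern was 80 calls in genes with under 10 reads per library. They were 1.7% of such tested genes, against 6.6% called among genes with 10 or more reads. Their median length was 0.153 of that of the other called genes, but the filter on mean TPM alone leaves few-read genes short (618 bases among all tested), so this test decides nothing and whether short length is the cause stays open.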

How the results depend on the processing

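The filter on recovered reads and voom were chosen after the data were seen. No call reversed. Of 261 results for 87 genes picked from the naming rule, 197 kept their side of the threshold in every alternative, 46 were lost and 18 gained in some, and of the 738 results of all 246 genes the counts were 616, 64 and 58; of 96 list results the counts were 62, 15 and 19. The cause of each change below was not tested, except that fewer genes pass a fold limit by construction.

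With each library left out in turn, calls between livers labelled DKO and control livers ran from 333 to 527 higher and 242 to 415 lower, re-expression against DKO from 1 to 7 and 4 to 10, and re-expression against control from 125 to 200 and 50 to 124. Genes called back ran from 4 to 15, the median share from 0.263 to 0.317, and lists called from 5 to 9, 1 to 2 and 2 to 9.

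Higher calls between DKO and control, 537, became 330 with 8 libraries and 331 with a 1.5-fold limit. Lower calls, 421, became 241 with 8 libraries and 639 with voom. For re-expression against DKO, the 5 higher calls became 8 with the top 20 genes left out of the total, 11 with 8 libraries, 13 with weights, 9 with at least 10 reads and 14 with voom, and the 8 lower calls 23 with weights and 22 with voom. For re-expression against control, the 208 higher calls became 120 with 8 libraries, and the 119 lower calls 60 with 8 libraries and 284 with voom. The 12 genes called back became 30 with weights, 19 with at least 10 reads and 33 with voom. The share of calls that were higher in re-expression against control was 63.6%, and 51.9% with voom.

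The 9 lists called between DKO and control became 1 with an estimated correlation, the 2 for re-expression against DKO 7 with a preset and 1 with an estimated correlation, and the 7 for re-expression against control 4 with size factors, 3 with 8 libraries, 3 with voom, 11 with a preset and 1 with an estimated correlation.

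With the replicate block, re-expression against DKO gave 3 higher and 5 lower, re-expression against control 64 lower, 7 genes were called back, and lists called were 1 and 2. The numbers are not taken to pair livers: deviations of same-numbered livers correlated from -0.0688 to -0.0215 for DKO with control and from -0.0507 to -0.0212 for re-expression with DKO. Between re-expression and control they were 0.137, 0.0384, 0.0699 and 0.0879, each best with its own number, a hint from the data alone. Depth limits genes with few reads, of which 4603 tested genes had under 10 per library.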

Other observations

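No test in this part was chosen after its result was seen, but the genes and lists singled out were picked after their values were seen. Cholesterol synthesis genes were not called as a list by fry: 20 of 23 had a negative log2 change in livers labelled DKO (median -0.44, fry adjusted p = 0.314), with 1 called lower and 1 called higher, Insig2, which restrains the pathway and rose by 2.06. Adjusted over the list alone, 9 were lower and 1 higher. In re-expression against DKO 22 of 23 were positive (median 0.37, fry adjusted p = 0.606) and 0 were called by limma. In re-expression against control 7 were positive and 16 negative (median -0.09, fry adjusted p = 0.99), and 1 was called higher. The list was called between livers labelled DKO and control without DKO replicate 1 (0.0418), and with a preset correlation in that comparison (0.00036) and in re-expression against DKO (2.51e-06).

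In the stress response list Asns, the asparagine synthetase gene, fell from 30.1 ± 10.9 to 4.85 ± 2.35 TPM in livers labelled DKO while the list's median was -0.02 (SD, n = 4, fry adjusted p = 0.91). Of its 14 genes 1 was called lower and 2 higher, Manf and Hspa5, whose calls were lost in 10 and 12 of 25 alternatives. Zbp1, a sensor gene of the interferon response, fell by 1.55 (adjusted p = 0.00157) with 1 of 16 genes of its list called. Of the 10 periportal hepatocyte genes 1 was called lower, the amino acid transporter gene Slc7a2, at 385 ± 16.8 and 224 ± 12.4 TPM. Of the 12 male-biased liver genes 2 were called higher and 1 lower (fry adjusted p = 0.764), with Serpina12 up by 1.68.

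In the authors' deposited table, comparison 1 called 736 genes higher and 766 lower, and its fold changes correlated across genes with those of livers labelled DKO against control (0.989). In the authors' deposited table, comparison 2 called 35 and 37 genes and correlated with re-expression against DKO (0.986). In the authors' deposited table, comparison 3 gave 157 genes higher and 53 lower, with log2 fold changes of 1.10 for Nr1d1, 2.11 for Npas2, 0.70 for Cry1 and 0.41 for Arntl.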
